A study of Mus musculus with 8 samples.

How the data were processed

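Quadriceps muscle RNA from mice aged 3 months was measured by 3′ mRNA sequencing (QuantSeq FWD), a method in which each read comes from near the 3′ end of a polyadenylated transcript, so that read number does not scale with transcript length by design. Control mice (4 libraries) carried floxed Gpcpd1 without the Mck-Cre transgene. Knockout mice (4 libraries) carried floxed Gpcpd1 with Mck-Cre, a Cre recombinase under the muscle creatine kinase promoter. The groups were taken from the genotype labels, and replicates were numbered in accession order, which pairs no samples. The labels give each library its own number but do not say that each came from a different mouse, nor state sex, litter or batch, so p-values measure the spread between these libraries.

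Per the file headers, the authors deposited raw read counts per Ensembl gene, 1 table per library, with no normalization. The submitters' processing notes name Bowtie2 2.3.4.1, featureCounts and Subread 1.6.2, with the genome builds GRCm38 and mm10. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap another gene, lie antisense to one or have near-identical copies therefore have uncertain counts. Each table holds 54532 genes, of which 54409 were matched to names and coordinates in the GENCODE M21 annotation of GRCm38.

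Library totals ran from 4404116 to 5405999 reads. At these totals a floor of 3 reads corresponds to between 0.555 and 0.681 CPM (reads scaled to a common library total), and this floor covers counting error only. Duplicate libraries were checked by a chi-square test of read counts over genes with at least 10 reads in a pair. The chi-square per degree of freedom was 2.33 to 7.96 in the 12 pairs of the same genotype and 10.8 to 18.7 in the 16 mixed pairs, so no pair agreed within sampling noise and all 8 libraries were counted separately.

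Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 10691 genes holding between 99.5% and 99.6% of each library's reads. Libraries were scaled by TMM, and genotype was tested with edgeR's robust quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Standard errors (SE) are the log2 fold change divided by the square root of F. CPM values use TMM-scaled totals, and means are given with the standard deviation (SD) over 4 libraries. Library measures and the Gpcpd1 level were also tested by exact two-sided permutation of the 8 libraries, for which the smallest possible p is 0.0286.

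Before the data were examined, 45 gene lists were written from general knowledge of muscle, covering metabolism, contraction, stress responses and markers of other cell types. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 42 lists tested. The sex-linked list was kept out of the tests, and the lymphocyte and the neutrophil and mast cell lists had 3 tested members each. Camera was repeated with a correlation estimated per list, and fry was run beside it. The directional p of fry asks whether the genes of a list move one way on balance, its mixed p asks whether they change in either direction, and neither compares the list with other genes.

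The rule for genes named in the text, fixed at the same time, took Gpcpd1, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, the 10 genes of lowest p, up to 4 changed members of lowest p per list, and 2 members of lowest p, as values only, for a called list with fewer than 2 changed members. Predicted genes, pseudogenes and sex-linked genes were left out of the parts ranked by fold or p. The rule took 134 genes, some of which are not reported here.

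The procedure was tested on simulated counts with the means, dispersions and library sizes of the 10691 genes, with 200 genes changed in each of 5 simulations. For the knockout against control comparison it recovered 10.8% of genes changed 1.25-fold, 46.8% at 1.5-fold, 79.2% at 2-fold and 98.4% at 4-fold. Of all calls, 6.37% were false. With no changed gene, at most 3 genes and 0 lists were called, and a simulated list of 30 genes raised 1.25-fold was called in 5 of 5 simulations. The simulated genes were independent of each other, so these figures do not cover correlation between genes. They also rest on 200 changed genes, fewer than the 1675 called in the data, and the adjusted p depends on that number, so they may differ for the data.

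Alternatives to the main analysis were DESeq2 1.42.0, limma voom with and without sample weights, edgeR without robust estimation, other scalings, other low-count filters, thinning of all libraries to 4404116 reads, the library number as a covariate, 1 surrogate variable from sva 3.50.0, other thresholds, removal of mitochondrially encoded or abundant genes, other list tests and leaving out each library. Knockouts were numbered 11 to 14 and controls 9, 10, 15 and 16, so a straight trend over the library number was balanced between genotypes. That covariate could hardly move the genotype estimates, and it does not test for an effect of the knockouts forming 1 block. Fits with the trend of counts on transcript length or on GC content removed were chosen after seeing the data.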

Results

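RNA from the quadriceps of mice aged 3 months was profiled in 8 libraries, 4 from control mice and 4 from mice lacking Gpcpd1 in muscle. Gpcpd1 encodes a glycerophosphodiesterase that splits glycerophosphocholine into glycerol phosphate and choline, and the study links this pathway to aging and glucose metabolism. The control libraries held between 4404116 and 5183079 reads and the knockout libraries between 4806806 and 5405999. Controls lacked the Cre transgene, so the presence of Cre changed together with the loss of Gpcpd1.

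The first comparison asked whether Gpcpd1 transcript was lost. Gpcpd1 (ENSMUSG00000027346, GRCm38 chromosome 2, 132529082 to 132587729, minus strand) fell from 149.7 ± 10.7 CPM in controls to 35.1 ± 3.45 CPM in knockouts (SD, n = 4 each). Control libraries 1 to 4 held 736, 771, 688 and 711 reads of Gpcpd1, and knockout libraries 1 to 4 held 145, 187, 193 and 181. The log2 fold change of Gpcpd1 was -2.09 (SE 0.10, edgeR adjusted p = 2.1e-13), and the knockout level was 23.5% of control. An exact two-sided permutation test of the Gpcpd1 level gave p = 0.0286, the smallest value this design allows. The floxed exons are not given in the sources used here, and 3′ reads can lie outside the deleted part, so these reads measure the 3′ end of the transcript and not the deletion.

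The second comparison asked which genes differed with genotype. Car3, a carbonic anhydrase abundant in muscle and fat, rose from 3219 ± 420 to 10899 ± 412 CPM (SD, n = 4 each), a log2 fold change of 1.76 (SE 0.09). On the same scale, Kbtbd12 (log2 fold change 1.91, SE 0.09), Tceal7 (2.92, SE 0.14), Tbkbp1 (1.88, SE 0.12) and the selenoprotein gene Msrb1 (1.17, SE 0.08) rose as well. The sulfhydryl oxidase gene Qsox1 rose from 77.8 ± 5.71 to 178.5 ± 13.7 CPM. All of these, like Car3, were among the 10 genes of lowest p once predicted genes, pseudogenes and sex-linked genes were left out. Aebp1 fell from 151.2 ± 22.2 to 51.8 ± 5.34 CPM (log2 fold change -1.55, SE 0.11), and the histone gene Hist1h4i fell from 103.5 ± 12.9 to 24.3 ± 2.17 CPM, although histone genes have near-identical copies and its count is uncertain. In total 1675 of 10691 tested genes (15.7%) changed by edgeR's quasi-likelihood test at an adjusted p of 0.05, 948 higher and 727 lower in the knockout. This balance depended on the scaling: with library totals alone 829 were higher and 901 lower, while under each other alternative more were higher.

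Of the changed genes, 260 differed by at least 2-fold, 208 of them higher and 52 lower. In 1432 of the 1675 the knockout libraries did not overlap the control libraries. Among all tested genes 19.2% did not overlap, against 2.86% given by chance. The first principal component held 39.6% of the variance between libraries and separated the genotypes.

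**Figure D1:**
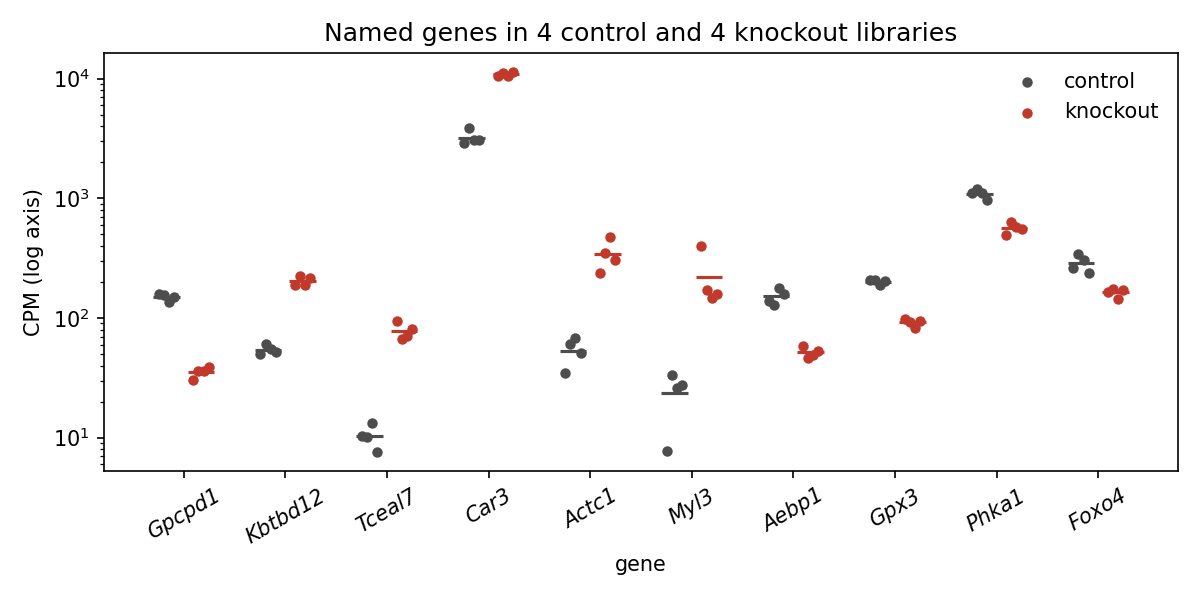
CPM (log axis) of 10 named genes in each of 4 control and 4 knockout libraries, with points for libraries and lines for group means. Gpcpd1 lay between 134.7 and 158.5 CPM in controls and between 30.4 and 38.6 CPM in knockouts, and Myl3 in knockout 1 stood at 398.4 CPM.

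Of the 10 named genes with the largest rises, Myl3 (log2 fold change 3.20, SE 0.53) and Tceal7 had control means of 23.7 and 10.3 CPM, and the others were lower in control muscle. Gpr27, an orphan G protein-coupled receptor gene, rose from 0.520 ± 0.228 to 11.8 ± 1.75 CPM (SD, n = 4 each; log2 fold change 4.46, SE 0.30). Controls 1 to 4 held 4, 2, 2 and 2 reads of Gpr27, around the floor of 3 reads, so the size of its rise is uncertain. Prkcz, an atypical protein kinase C gene, rose from 0.773 ± 0.200 to 9.40 ± 1.45 CPM (log2 fold change 3.56, SE 0.29). It had 4, 5, 3 and 3 reads in controls 1 to 4, also around that floor, so the size of its rise is uncertain too. Fibcd1 had 1 read in the 4 controls and 50 in the 4 knockouts, a ratio of 48.4 with a 95% counting interval of 8.30 to 1950. Pfn4 had 3 and 57 reads, a ratio of 18.4 with an interval of 5.99 to 91.8. Snhg11 (3.28, SE 0.37), the glutamate transporter gene Slc1a1 (2.93, SE 0.27), Shisal1 (2.88, SE 0.48) and Cux2 (2.73, SE 0.25) also rose on the log2 scale. In controls 1 to 4, Snhg11 had 2, 2, 2 and 10 reads and Shisal1 3, 0, 5 and 1, most of them at or below the floor of 3 reads.

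Besides Gpcpd1, Hist1h4i and Aebp1, the largest falls among the named genes on the log2 scale were in Mss51 (-1.88, SE 0.20), a muscle mitochondrial gene, Tpx2 (-1.64, SE 0.28), the zinc transporter gene Slc30a2 (-1.64, SE 0.25), Ube2cbp (-1.61, SE 0.36), the potassium channel gene Kcng4 (-1.56, SE 0.16) and Zfp773 (-1.50, SE 0.28). Amd2 (-1.63, SE 0.42) has a near-identical copy and an uncertain count.

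**Figure D2:**
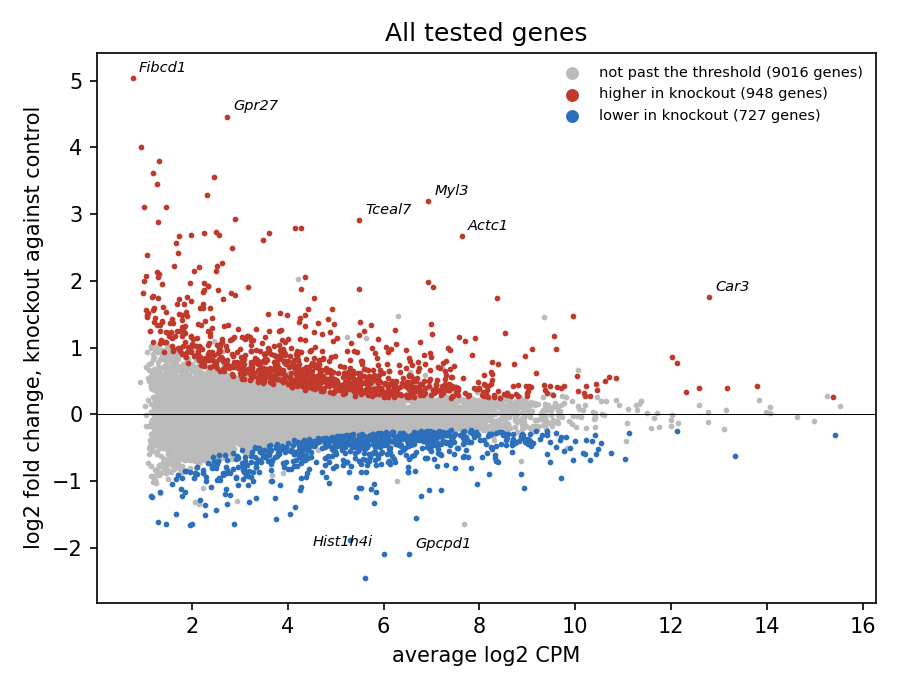
Log2 fold change, knockout against control, plotted against average log2 CPM for 10691 tested genes, one point per gene. Of these, 948 were higher and 727 lower at an edgeR adjusted p of 0.05, and Car3 stood out among abundant genes with a log2 fold change of 1.76.

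The third comparison asked which of the gene lists differed with genotype. Proteasome subunit genes, which build the complex that degrades ubiquitin-tagged proteins, rose: 17 of 29 tested members were higher and 0 lower, and 23 were higher when adjusted over the list alone. Psma7 (log2 fold change 0.59, SE 0.08), Psmd6 (0.56, SE 0.08), Psma6 (0.54, SE 0.09) and Psmb1 (0.46, SE 0.08) had the lowest p. The median log2 fold change was 0.35 and the camera adjusted p = 2.6e-09, with an adjusted p = 0.0916 with an estimated correlation.

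In the list of regeneration and embryonic muscle genes, 6 of 15 tested members were higher and 0 lower, and adjusted over the list alone 7 were higher and 1 lower. The cardiac alpha-actin gene Actc1, expressed in developing muscle, rose from 53.4 ± 14.4 to 341.1 ± 98.4 CPM (SD, n = 4 each; log2 fold change 2.67, SE 0.29). The imprinted non-coding genes H19 (1.23, SE 0.17) and Meg3 (1.00, SE 0.09) and the perinatal myosin gene Myh8 (0.96, SE 0.17) rose as well. The list did not move as a whole: 9 members had a log2 fold change above 0 and 6 below, the lowest at -1.65. The list's median was 0.42 and its camera adjusted p = 0.0016, with an adjusted p = 0.440 with an estimated correlation. The median was 0.25 without control 1 and 0.26 without knockout 1.

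Nuclear-encoded oxidative phosphorylation genes had 20 of 73 tested members higher and 0 lower, and 26 higher when adjusted over the list alone. Ndufb3 (log2 fold change 0.89, SE 0.11) and Cox5b (0.70, SE 0.11), subunits of complex I and complex IV, had the lowest p, followed by Ndufs4 (0.46, SE 0.09) and Cox6a2 (0.46, SE 0.09). The median was 0.18, the camera adjusted p = 4.2e-06, the adjusted p = 0.840 with an estimated correlation and the fry adjusted p = 0.0867. Relative to the control mean, the median member stood at 0.14, 0.21, 0.08 and 0.29 on the log2 scale in knockouts 1 to 4 and at 0.14 in control 2, so the groups overlapped. Single members differed more, and Ndufa1 and Atp5j, chosen after their values were seen, had 278 and 474 reads in knockout 1 against at least 723 and 895 in the other knockouts. The number of higher members was 22 without knockout 1 and 11 without knockout 4. Only 6 of 13 listed mitochondrially encoded genes were tested, and mitochondrially encoded genes held 0.180% to 0.329% of the reads of a library. None of the 6 passed the threshold, and their median was -0.12 (camera adjusted p = 0.377).

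Of 33 tested genes for pyruvate use and the tricarboxylic acid cycle, 10 were higher and 2 lower, and adjusted over the list alone 14 were higher and 3 lower. Me3, a mitochondrial malic enzyme gene (log2 fold change 0.67, SE 0.11), and Pdk1, whose product inhibits pyruvate dehydrogenase (0.64, SE 0.13), rose, while the pyruvate carboxylase gene Pcx fell (-0.46, SE 0.09). The median was 0.19 and the camera adjusted p = 0.0278, with an adjusted p = 0.753 with an estimated correlation. The call ended without control 3 (adjusted p = 0.0843), control 4 (0.0651) or knockout 4 (0.0987). The number of higher members was 6 without control 3 and 5 without control 4, knockout 2 or knockout 4.

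Insulin signalling genes had 9 of 34 tested members lower and 2 higher, with the same counts when adjusted over the list alone. The kinase gene Akt2 (log2 fold change -0.62, SE 0.09), the insulin receptor substrate gene Irs1 (-0.58, SE 0.12) and Foxo4, a transcription factor restrained by Akt (-0.81, SE 0.10), fell. Grb14, an inhibitor of the insulin receptor, rose (0.82, SE 0.17). The median was -0.17 and the camera adjusted p = 0.0191, with an adjusted p = 0.318 with an estimated correlation.

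Atrophy and autophagy genes had 8 of 35 tested members lower and 1 higher, and adjusted over the list alone 12 were lower and 3 higher. The autophagosome gene Map1lc3a (log2 fold change -0.52, SE 0.08), the ubiquitin ligase gene Fbxo31 (-0.51, SE 0.09) and the autophagy initiation gene Becn1 (-0.46, SE 0.09) fell. The median was -0.17 and the camera adjusted p = 0.0191, with an adjusted p = 0.521 with an estimated correlation.

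Markers of macrophages had 3 of 10 tested members lower and 0 higher, and 4 lower when adjusted over the list alone. Cd163, a haemoglobin scavenger receptor gene (log2 fold change -0.75, SE 0.18), C1qb, a complement gene (-0.83, SE 0.21), and Csf1r (-0.59, SE 0.19), whose call was lost in 9 alternatives, fell. The median was -0.36 and the camera adjusted p = 0.0335, with an adjusted p = 0.840 with an estimated correlation and a fry adjusted p = 0.191. Relative to the control mean, the median member stood at -0.38, -0.39, 0.04 and -0.81 on the log2 scale in knockouts 1 to 4 and at -0.24, -0.12, 0.45 and 0.07 in controls 1 to 4, so the groups overlapped. The call ended without control 3 (adjusted p = 0.208), control 4 (0.0522) or knockout 4 (0.108), with a stricter filter of at least 5 CPM in 4 libraries (0.0544) and with 1 surrogate variable (0.0612).

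Glucocorticoid-responsive genes had 1 of 20 tested members lower, the glutamine synthetase gene Glul (log2 fold change -1.23, SE 0.14), also when adjusted over the list alone, and Zbtb16 had a value of -0.31 (SE 0.11). The median was -0.18 and the camera adjusted p = 0.0425, with an adjusted p = 0.840 with an estimated correlation. The median member stood at -0.06 in knockout 2 and at -0.16 in control 3 on the same scale, so the groups overlapped here too. The call ended without control 2 (adjusted p = 0.0658), control 4 (0.194), knockout 1 (0.0790), knockout 3 (0.105) or knockout 4 (0.0987). It also ended by fry (adjusted p = 0.191), without genes that several lists hold (0.206), with 1 surrogate variable (0.111), with voom quality weights (0.0750), with the stricter filter (0.0661), with the GC trend removed (0.0535) and with library totals alone (0.0520). Without knockout 2 and without control 3 the number of lower members was 5 and 6.

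**Figure D3:**
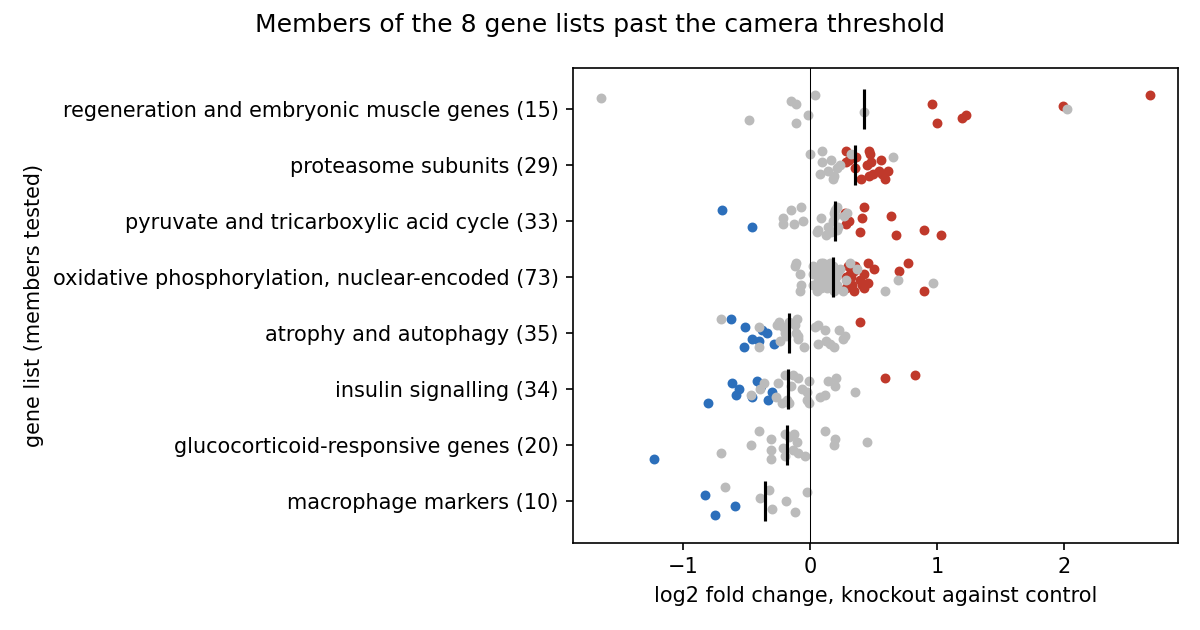
Log2 fold change, knockout against control, of each tested member of the 8 gene lists past the camera threshold, with the number of members in brackets. Red points rose, blue points fell, grey points did not pass the edgeR threshold and black lines mark medians, which ran from -0.36 for macrophage markers to 0.42 for regeneration and embryonic muscle genes.

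The other 34 lists did not pass the camera threshold, though many held changed genes. Since 15.7% of all tested genes changed, changed members alone do not mark a list as different from other genes. In glucose uptake and glycogen metabolism 2 of 30 tested genes were higher and 3 lower, the same as when adjusted over the list alone (camera adjusted p = 0.0964). The phosphorylase kinase gene Phka1 fell from 1092 ± 97.0 to 564.1 ± 60.4 CPM (SD, n = 4 each), and hexokinase 2 (Hk2) had a log2 fold change of -0.44 (SE 0.08). In glycolysis 4 of 20 were higher and 1 lower, and 2 lower when adjusted over the list alone, with rises in Pfkfb1 (1.02, SE 0.12) and Ldhb (1.12, SE 0.15; camera adjusted p = 0.644). In choline and glycerophosphodiester metabolism, the pathway of Gpcpd1, 4 of 30 were higher and 1 lower, also when adjusted over the list alone. Pld1, a phospholipase D gene, rose (0.97, SE 0.23) and Pcyt1a, the rate-limiting gene of phosphatidylcholine synthesis, fell (-0.29, SE 0.08; camera adjusted p = 0.641), a fall that was no longer called without knockout 3 (edgeR adjusted p = 0.0553).

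In fatty acid uptake and oxidation 7 of 42 genes were higher and 2 lower (9 and 4 adjusted over the list alone), with rises in Eci1 (0.76, SE 0.11), Hadh (0.45, SE 0.09) and Fabp3 (0.55, SE 0.11; camera adjusted p = 0.319). In fatty acid and triglyceride synthesis 3 of 22 were higher and 2 lower, the same adjusted over the list alone, with rises in Thrsp (1.39, SE 0.12) and Acss2 (0.79, SE 0.18; camera adjusted p = 0.606). In amino acid and creatine metabolism 4 of 31 were higher and 6 lower (7 and 7 adjusted over the list alone), with a rise in Gamt (0.97, SE 0.16) and a fall in Smox (-0.69, SE 0.09; camera adjusted p = 0.821). In sterol synthesis 1 of 18 was higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.960).

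Slow fibre genes had 2 of 5 tested members higher and 0 lower, also when adjusted over the list alone. These were the slow myosin light chain gene Myl3, from 23.7 ± 11.1 to 219.0 ± 120 CPM (SD, n = 4 each), and the calsequestrin gene Casq2 (0.56, SE 0.14; camera adjusted p = 0.226). Fast fibre genes had 2 of 15 higher and 3 lower (5 and 4 adjusted over the list alone), with Mylpf (0.43, SE 0.09) higher and Mylk2 (-0.69, SE 0.08) and the fast myosin gene Myh4 (-0.31, SE 0.09) lower (camera adjusted p = 0.960). In excitation-contraction coupling 2 of 24 were higher and 6 lower (4 and 6 adjusted over the list alone), with Jph2 at -0.39 (SE 0.09; camera adjusted p = 0.815). Among neuromuscular junction and denervation genes 4 of 17 were higher and 1 lower (6 and 1 adjusted over the list alone), with acetylcholinesterase (Ache) at 2.61 (SE 0.24), the acetylcholine receptor gene Chrnb1 at 0.69 (SE 0.15) and Prkag3 at -0.80 (SE 0.09; camera adjusted p = 0.226).

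The heat shock list had 7 of 23 higher and 2 lower, also when adjusted over the list alone, with rises in the small heat shock genes Hspb6 (1.48, SE 0.12), Hspb1 (0.98, SE 0.12) and Cryab (0.97, SE 0.12) and a fall in Hspb8 (-0.42, SE 0.09; camera adjusted p = 0.123). Oxidative stress genes had 4 of 29 higher and 4 lower (7 and 4 adjusted over the list alone), and the secreted glutathione peroxidase gene Gpx3 fell from 201.3 ± 9.01 to 92.0 ± 7.07 CPM (camera adjusted p = 0.961). The osmotic stress list had 1 of 20 higher and 3 lower (2 and 5 adjusted over the list alone), with the water channel gene Aqp4 at 1.07 (SE 0.23) and the cotransporter gene Slc12a2 at -0.84 (SE 0.09; camera adjusted p = 0.377). Circadian genes had 1 of 21 higher and 3 lower, also adjusted over the list alone, with Rora at -0.71 (SE 0.08; camera adjusted p = 0.358). Myokines had 1 of 14 higher and 4 lower (1 and 5 adjusted over the list alone), with Fstl3 at 1.64 ± 0.319 CPM in controls and 3.95 ± 0.566 in knockouts and Gdf11 at -0.88 (SE 0.14; camera adjusted p = 0.123).

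The integrated stress response list had 2 of 19 higher and 2 lower, with Atf5 at 0.54 (SE 0.09; camera adjusted p = 0.977). Senescence and p53 targets had 1 of 22 higher and 1 lower, and the cell cycle inhibitor gene Cdkn1a rose (1.26, SE 0.18; camera adjusted p = 0.961). Cdkn1a was also 1 of 2 higher genes among 19 reported to rise with age in rodent muscle, of which 0 were lower (camera adjusted p = 0.977). Immediate early genes had 1 of 20 higher and 1 lower (camera adjusted p = 0.815), inflammatory cytokines and receptors 2 of 19 higher (0.815), the interferon response 1 of 26 higher (0.990), endoplasmic reticulum chaperones 1 of 19 lower (0.960). Counts adjusted over the list alone were the same for these 7 lists. Extracellular matrix genes had 2 of 34 lower, and 1 when adjusted over the list alone (camera adjusted p = 0.570). Cytosolic ribosomal proteins, whose many copies make counts uncertain, had 1 of 48 higher and 2 lower, and 0 when adjusted over the list alone (camera adjusted p = 0.377).

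Among markers of other cell types, the macrophage list alone passed the camera threshold. Adipocyte markers had 1 of 10 higher, Car3 (camera adjusted p = 0.123), pericyte and smooth muscle markers 1 of 14 higher, Lmod1 (0.815), and tendon cell markers 1 of 8 higher, Thbs4 (0.961), whose own call was lost in 11 alternatives. Fibro-adipogenic progenitor markers had 1 of 14 higher, Smoc2 (0.76, SE 0.13), and 3 lower, among them Pi16 (-0.59, SE 0.11; camera adjusted p = 0.213). Counts adjusted over the list alone were the same for these 4 lists. Endothelial (15 tested, camera adjusted p = 0.644), Schwann cell and nerve (7, 0.815), satellite cell (7, 0.815) and erythrocyte markers (6, 0.508) had 0 changed members, as had the lymphocyte list (3 tested), the neutrophil and mast cell list (3 tested) and the sex-linked list (4 tested), none of which was given a list test.

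In 12 of these lists the median, the mean and the camera direction differed in sign, namely glycolysis, sterol synthesis, excitation-contraction coupling, senescence, the integrated stress response, endoplasmic reticulum chaperones, oxidative stress, interferon, amino acid and creatine metabolism, and the adipocyte, pericyte and satellite cell markers. With an estimated correlation 0 of 42 lists passed by camera, while 8 passed with the preset one, 10 by the directional p of fry and 32 by its mixed p. Fry alone called neuromuscular junction and denervation genes (fry adjusted p = 0.0166) and choline and glycerophosphodiester metabolism (0.0427), each higher. It alone also called myokines (fry adjusted p = 0.0166), circadian genes (0.0348) and glucose uptake and glycogen metabolism (0.0348), each lower. When the 8 libraries were divided into 4 and 4 in all 35 ways, 10 divisions, the real one included, gave at least 8 lists by camera with the preset correlation.

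The fourth comparison concerned the libraries as a whole. Knockout libraries held 17296 ± 298 genes with at least 1 read and control libraries 16787 ± 172 (SD, n = 4 each; exact permutation p = 0.0286, Benjamini-Hochberg p = 0.114 over 4 measures). The 20 most abundant genes took 38.5% ± 0.363 of knockout reads and 37.3% ± 1.12 of control reads (exact permutation p = 0.0571, adjusted 0.114). Mitochondrially encoded genes took 0.216% ± 0.0440 and 0.264% ± 0.0495 (exact permutation p = 0.257, adjusted 0.343), and library totals did not pass either (p = 0.343 by exact permutation). None of the 4 measures passed after adjustment. With a smallest possible p of 0.0286, 1 measure alone could not pass this adjustment, so the outcome does not show that the libraries were alike. For detected genes the groups did not overlap, with at least 16986 in each knockout and at most 16984 in each control.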

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

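The tests weighed here for Myl3 were chosen after its values were seen. Among the named genes and the library measures, 276 groups of 4 libraries were examined, and in 20 the highest or lowest library stood far from the others, its gap to the nearest divided by the whole range lying above the 95% critical value for 4 values. Chance gives about 13.8 such groups, and the 20 were spread over 7 of the 8 libraries, with 4 each in knockout 1 and knockout 3.

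In control muscle, Gpr27 stood highest in control 1 at 0.862 CPM against at most 0.420 in the others (ratio 0.923), and Rpl15 also in control 1 at 12.5 CPM (0.957). The Gpr27 values were 4 reads against 2 in each other control, a gap within counting error. Dgat2 was lowest in control 1 at 17.9 CPM (0.866). Snhg11 was highest in control 4 at 2.10 CPM (0.958), where Ier3 at 42.2 CPM (0.846) and Fdft1 at 27.5 CPM (0.858) were lowest. Hspb1 was highest in control 2 at 60.4 CPM (0.912). In control 3, Gpx3 at 188.0 CPM (0.838) and Nfil3 at 5.68 CPM (0.904) were lowest, and the 1 control read of Fibcd1 lay there (ratio 1).

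In knockout muscle, Thrsp at 73.7 CPM (ratio 0.946), Myl1 at 10757 CPM (0.834) and Myl3 at 398.4 CPM (0.852) were highest in knockout 1, and Tpi1 at 519.1 CPM (0.840) was lowest there. In knockout 3, Hspb1 at 75.6 CPM (0.918), Zfp773 at 1.11 CPM (0.957), Irs1 at 27.5 CPM (0.966) and Ier3 at 32.9 CPM (0.951) were lowest. In knockout 2, Hist1h4i was lowest (0.923), against 25.2 to 25.6 CPM in the others, and Tnfrsf1a highest at 26.7 CPM (0.841).

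Myl3, a slow-muscle light chain gene, rose in all 4 knockout libraries, most in knockout 1, which also held 45 of the 58 knockout reads of the slow light chain gene Myl2. A larger share of slow muscle in the dissected piece would bring the other abundant slow genes, but Myh7, Myl2, Tnnt1, Tnnc1 and Tnni1 together gained 3.83% of the CPM that Myl3 gained, and 0.278% without knockout 1, which argues against that explanation for the whole rise. Without knockout 1 the log2 ratio of mean Myl3 CPM was 2.75. Regenerating fibres stay open, since satellite cell markers with Myh3 and Myod1 had a median log2 fold change of 0.0200 over 9 genes that went both ways, between -0.48 and 0.30. A hypothesis that remains is an effect of genotype on Myl3 in the fibres themselves, which these data do not separate from an effect of the Cre transgene.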

How the results depend on the processing

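The fits with the transcript length or GC trend removed were chosen after seeing the data. Gpcpd1 kept its direction and stayed past the threshold under every alternative run. The count of changed genes moved by over 1.5 times only with stricter thresholds, which by construction call fewer genes: 996 (594 higher, 402 lower) at an adjusted p of 0.01 and 651 (434 higher, 217 lower) against a minimum change of 1.2-fold. Leaving out 1 library gave 1307 to 1728 changed genes, and these included 75.0% to 87.9% of the main calls. DESeq2 called 1328 genes and sva 2053. With library totals alone 47.9% of 1730 calls were higher.

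The number of lists past camera was 13 without a low-count filter, 0 with an estimated correlation, and 5 to 10 when 1 library was left out, with 5 without control 4 and 5 without knockout 4, and the cause was not tested. The difference in detected genes, knockout minus control, had an unadjusted exact permutation p of 0.0286 and did not pass after adjustment (0.114), as 1 measure alone at that p could not. It was 376.6 to 612.3 when 1 library was left out, with an unadjusted p of 0.0571 without any 1 control or without knockout 3, and 352.8 after thinning to 1 depth (unadjusted p = 0.0571). The difference in the share of the 20 most abundant genes was 0.621 to 1.46 percentage points when 1 library was left out, and passed unadjusted only without control 2, at 1.46. Control 2, at 38.21%, was the only control within the knockout range of 38.00% to 38.85%, so without it the groups did not overlap. Why its share was higher was not tested.

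Of the 133 other named genes, 111 kept their call in every alternative in which they were tested. Genes that an alternative filtered out were not counted there. Fibcd1, at most 3.20 CPM in any library, could not be tested with the filter of at least 5 CPM in 4 libraries. In 21 genes a call was lost in at least 1 alternative, among them Ier3, Tnfrsf1a, Vldlr, Slc6a6, Chpt1, Fdft1, Gbe1, Pcyt1a, Chrna1, Tnfrsf12a, Ccn2, Lox, Rpsa, Mthfd2, Dcn, Csf1r, Rpl15, Thbs4, Rpl17 and Clec3b. Zbtb16 gained one. No paired analysis was possible because the replicate numbers were given in accession order. Thinning all libraries to the shallowest gave 1619 changed genes.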

Other observations

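Of 554 tested non-coding genes 99 were higher and 30 lower, so that 76.7% of the changed ones were higher, against 54.7% of changed protein-coding genes (837 higher and 692 lower, Fisher's exact p = 7.4e-07 across genes, which are not independent). Among long intergenic RNAs 38 were higher and 7 lower, and among antisense genes, whose counts are uncertain, 27 and 7. Of 90 tested genes within 10 Mb of Gpcpd1, 11.1% changed, against 15.7% elsewhere (Fisher's exact p = 0.306 across genes).

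Tests chosen after the result was seen are those of transcript length, of the fibre share of RNA and of depth. The count of 1675 changed genes was the highest of the 35 ways to divide the 8 libraries into 4 and 4. Only 1 of the 35, the real one, reached it, with 26 genes in the highest other. A rank of 1 in 35 is the best this design allows, so this test alone cannot exclude chance for that count. The other divisions mix the genotypes, so a difference between the real groups widens their spread and can lower their counts. The gap between 26 and 1675 therefore adds no strength. For the count of lists, 10 of the 35 divisions gave at least the 8 lists of the real one. The highest other gave 15, so chance cannot be excluded for the number of lists either.

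The same 35 permutations of the libraries were applied to each called list. In this exact permutation a camera p as small came in 1 of 35 divisions, the real one, for proteasome subunits (p = 6.2e-11, lowest other 1.6e-08) and for regeneration and embryonic muscle genes (p = 0.00011, lowest other 0.0013). A rank of 1 in 35 is the best this design allows. It would not stand after allowance for the 42 lists tested, from which these were taken for a small camera p in that division. Chance is therefore not excluded for them. A camera p as small came in 3 divisions for insulin signalling, 4 for atrophy and autophagy, 7 for pyruvate and the tricarboxylic acid cycle, 10 for nuclear-encoded oxidative phosphorylation, 14 for glucocorticoid-responsive genes and 16 for macrophage markers, so chance cannot be excluded for those lists.

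Proteasome and oxidative phosphorylation genes have short transcripts, with median lengths of 1819 and 1005 bases against 3436 for all tested genes. The proteasome median of 0.35 lay above all of 10000 random lists matched on transcript length and mean expression (percentile 100). The oxidative phosphorylation median of 0.18 lay at percentile 99.94. The matched lists had medians of 0.059 and 0.068, so they rose slightly too. Their genes were drawn independently, while the estimated correlation within a list was 0.04 for the proteasome and 0.40 for oxidative phosphorylation. For the proteasome the values argue against length as the whole cause. For oxidative phosphorylation the percentile cannot decide, because genes that move together widen the spread of a list median. For oxidative phosphorylation, chance stays open, with 10 of 35 divisions, and so does a larger share of RNA from muscle fibres: 39 fast fibre and excitation-contraction genes had a median of 0.0272, below the list (permutation p = 0.00042 with genes shuffled), but by less than their SD of 0.36, and they ran from -0.69 to 1.46. Marker medians of other cell types went both ways, below 0 for neutrophils and mast cells (-0.55, 3 genes), macrophages (-0.36), fibro-adipogenic progenitors (-0.26), tendon cells (-0.25), erythrocytes (-0.14), pericytes and smooth muscle (-0.08), endothelium (-0.04) and adipocytes (-0.02), and above 0 for Schwann cells and nerve (0.19), lymphocytes (0.15, 3 genes) and satellite cells (0.02). For the proteasome chance is not excluded after allowance for the lists tested. A hypothesis, not tested here, is that loss of Gpcpd1, or Cre itself, may raise its subunits together.

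The excess of higher calls among non-coding genes may come from their low expression: protein-coding genes drawn at the same expression had a median of 66.7% higher calls, and the observed 76.7% lay at percentile 94.22 of 10000 draws. Background reads, such as those from genomic DNA, stay open. The mean gain per untested gene was 0.233% of the median gain of the non-coding genes that rose, below a bound set in advance, but that bound was wrong because the count filter and the choice of risen genes make a small ratio by design. The share of reads in untested genes was 0.407% ± 0.0181 in controls and 0.458% ± 0.0156 in knockouts (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). Depth cannot be told apart as a cause of the detected gene count: after thinning the difference was 352.75, with an exact permutation p of 0.0571.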
